A study of Homo sapiens with 48 samples.

How the data were processed

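Per the labels' protocols, libraries of experiment 1 were made with TruSeq v2 from 50 ng of RNA (80 ng for stem cells) and read as single 51 bp reads on a HiSeq 2500, and those of experiment 2 with the LM-Seq protocol. The authors mapped reads to 19084 RefSeq genes on hg19 with Bowtie 0.12.9, allowing 2 mismatches in a 28 bp seed and dropping reads with over 200 alignments. These aligner settings are stated for experiment 1 only. Per the submitters' processing notes base calling used CASAVA 1.8.2 and quantification used RSEM. For experiment 1 the notes give RSEM 1.1.21 and the extraction protocol gives 1.2.3, while the notes for experiment 2 give 1.2.3, and the files used here did not settle which was run. The deposited expected counts of RSEM were used for tests and the deposited TPM for levels. Reads were not mapped again, and the genome reference at hand was of another build, so no position in the genome was used.

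Per the labels' protocols, gels held 40 mg/mL of 8-arm PEG of 20 kDa, a peptide crosslinker that matrix metalloproteinases can cleave (35 to 60% crosslinking) and 0 or 2 mM of the adhesion peptide CRGDS. They were set with a photoinitiator and 2 min of light near 365 nm while holding the cells. The labels do not say whether gels for culture on top were set before cells were added. H1-EC1 came from H1 and H1-EC2 from a reporter line of H1 with another mesoderm medium, so the 2 experiments were not pooled.

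The median library held 9315956 expected counts in experiment 1 and 14382472 in experiment 2, and the common coefficient of variation between duplicates in experiment 2 was 0.327. Every column of the deposited matrices was matched to a sample by its label, and 0 were left unmatched. In the TPM table of experiment 2, 28 gene symbols had been turned into dates and these genes have no level here. Left out of all tests were 45 sex-linked symbols. In experiment 1 the stem cell column departed from the other columns on 561 gene entries, and these were left out of the comparison with stem cells.

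Comparisons, gene lists, filters and the rule for naming genes were fixed before the data were examined. Expected counts were rounded and filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, scaled by TMM and fitted with the quasi-likelihood model, 1 fit of all 18 libraries for experiment 2 (9 residual degrees of freedom) and a fit for each comparison in experiment 1. Blocks were the day or the cell type. Genes with a Benjamini-Hochberg adjusted p below 0.05, taken over all genes of a comparison, were called. The mixture of monocultures was built in CPM with a pseudocount of 1, its share was fitted over genes that differed at least 4-fold and had at least 20 CPM, and log2 ratios of 3 days were tested with limma-trend (limma 3.58.1) for genes with at least 5 CPM. Comparisons of single libraries used log2(TPM + 1) for genes with at least 5 TPM and gave counts over 2-fold without a test. The 27 gene lists were written from general knowledge and tested with camera at its preset correlation of 0.01, then with an estimated correlation and with fry. With an estimated correlation camera is limited by the residual degrees of freedom of the fit. In experiment 1 these were 2 for H1-EC1 against HUVEC1, Matrigel against PEG gel and PEG gel against plastic. A list could hardly pass there, so a call lost in these comparisons says little about the list. For single libraries the median of a list was placed among 10000 random lists of like expression. List members called with p adjusted over the list alone were counted beside those called over all genes.

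Genes were named as the 10 highest and 10 lowest log2 changes in the main comparisons (PEG gel against plastic and against Matrigel gel, and H1-EC2 against HUVEC2) and the 4 highest and lowest elsewhere, with a change of at least 1, a mean log2 CPM of at least 3 and levels that did not overlap, or the same direction in each block. The rule on overlap or direction was not applied to trends or to the interaction. Single libraries used the 5 highest and lowest with at least 20 TPM. Beside these stand a panel of 8 markers and up to 4 called members of each called list. Genes of the rule that share reads with a neighbour or copy, and most of those that lost their call in a fit without 1 library, were left out of the text for length. For genes at 0 in a group only levels are given.

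Alternatives run were RLE factors, no filter, DESeq2 1.42.0, replicate number as a block, only the groups compared, all 25 gels of experiment 1 in 1 fit, other pseudocounts and thresholds, and leaving out each library or day. The scripts were checked on simulated data with planted changes. In experiment 2 tests of 2 against 2 libraries found 29 to 42% of planted 2-fold and 75 to 88% of planted 4-fold changes with 2 to 13 false calls, and the interaction 6 and 58% with 7 false calls. In experiment 1 the test of PEG gel against plastic found 12 and 91% with 11 false calls. The others of experiment 1 found at least 89% and 100% (of 1.41-fold and 2-fold per day for the trends with day) with 13 to 39 false calls. For the trend with crosslinking the planted changes were 2-fold and 4-fold per unit in which its slopes are given. In the real data 0 genes called for crosslinking changed 2-fold per unit. Recovery of crosslinking changes as small as the real ones was therefore not tested. The largest error of a fitted share was 1.5 points. The simulated co-cultures were built from the same monoculture libraries that the mixture was then fitted with. Noise between separate libraries was therefore left out of the mixture check. Its share error and recovery do not measure the error in the real co-cultures. Raw reads and isoform values were not used here.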

Results

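Both kinds of endothelial cell in experiment 2 carried endothelial genes at high levels on every substrate. KDR, a VEGF receptor of endothelial cells, stood at 1406 ± 23.0 TPM in endothelial cells derived from H1 embryonic stem cells (H1-EC2) in PEG gel (mean ± SD, n = 2) and at 495 ± 55.1 TPM in umbilical vein endothelial cells (HUVEC2) in PEG gel. PECAM1, an endothelial junction protein, stood at 330 ± 38.2 and 516 ± 25.3 TPM in these 2 groups, and CDH5, the endothelial cadherin, at 305 ± 21.9 and 593 ± 68.3 TPM. VWF, which carries a clotting factor, was at 22.9 ± 6.35 TPM in H1-EC2 and 612 ± 25.0 TPM in HUVEC2. The pluripotency genes POU5F1 and NANOG were at 1.66 ± 2.34 and 0.43 ± 0.608 TPM in H1-EC2 in PEG gel. PDGFRB, a receptor of pericytes, was at 6.17 ± 2.03 TPM in H1-EC2 and 0.09 ± 0.014 TPM in HUVEC2. H1-EC2 also carried blood and epithelial genes, with median log2(TPM + 1) of 4.42 and 5.08 (blood) and 5.34 and 5.35 (epithelial) in the PEG gel duplicates. In HUVEC2 in PEG gel these were 0.091 and 0 (blood) and 0.24 and 0.25 (epithelial). Bulk levels do not tell which cells carried these genes, so not every change in H1-EC2 need lie within endothelial cells.

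Experiment 1 held 30 libraries, 1 for each condition: H1 stem cells, H1-EC1, HUVEC1, brain vascular pericytes and a co-culture of H1-EC1 with pericytes, on plastic, on or in Matrigel or in PEG gels. Experiment 2 held 18 libraries, duplicates of 9 groups taken on day 1. Its labels do not state medium or oxygen. Comparisons of substrates in experiment 2 may therefore also hold differences of medium or oxygen. Libraries held 4928957 to 12758359 expected counts in experiment 1 and 11973770 to 17782619 in experiment 2. Duplicates correlated at 0.926 to 0.975 (log2 CPM), lowest for H1-EC2 on PEG gel, whose replicate 1 lay apart on the third principal component (−52.5 against 11.7). The first component, 72.2% of the variance, separated H1-EC2 (−103 to −80.9) from HUVEC2 (70.7 to 79.2), and the second held 5.02%. The origin of the duplicates is not stated, so every p-value here measures only the spread between these samples, which may be technical. Changes are log2 fold changes from edgeR ± standard error with adjusted p (q), and levels are mean TPM ± SD. In edgeR fits each standard error was worked back as the absolute change over the square root of its F statistic. Genes named by size of change had levels of the 2 groups that did not overlap or, in blocked fits, the same direction in each block (trends and the interaction had no such rule).

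**Figure D1:**
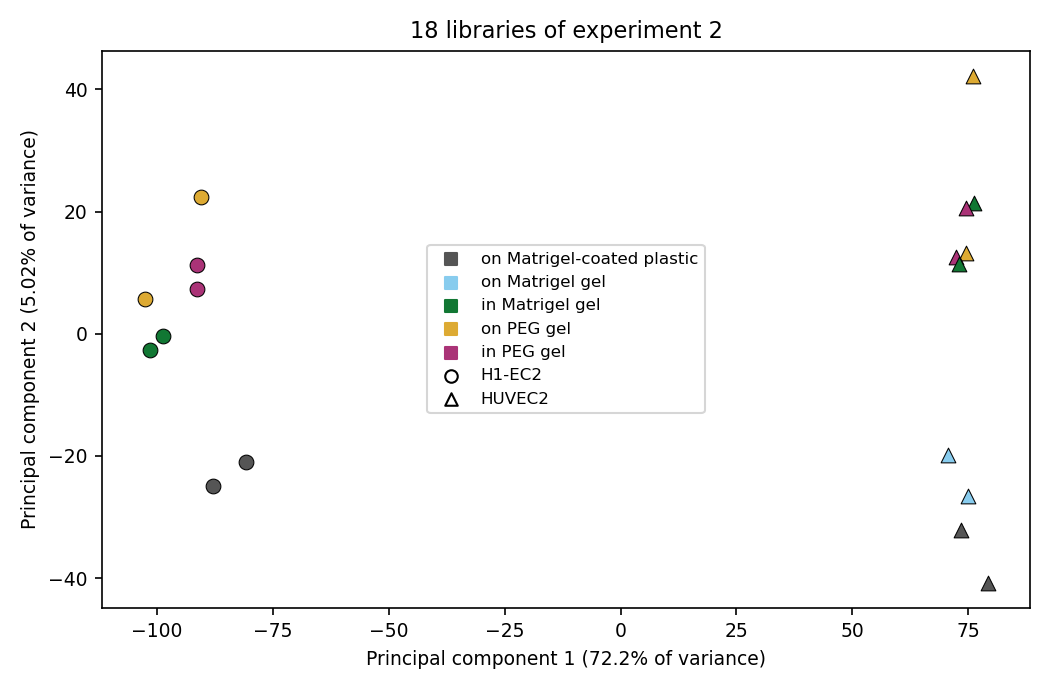
First and second principal components (percent of variance on the axes) of the 18 libraries of experiment 2, each point 1 library, with circles for H1-EC2, triangles for HUVEC2 and colours for the substrate. The first component, 72.2% of the variance, separated the cell types.

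H1-EC2 in PEG gel had more STC1 and HMOX1 and less of all 30 measured cell cycle genes than on coated plastic (n = 2 per group). STC1, a secreted glycoprotein, rose by 3.91 ± 0.38 (268 ± 39.5 against 17.5 ± 7.36 TPM, q = 1.0e-05). HMOX1, the heme oxygenase, rose by 3.17 ± 0.40 (444 ± 95.5 against 48.2 ± 5.0 TPM, q = 0.00012). CYP1A1 and CYP1B1, cytochrome P450 enzymes, rose by 3.63 ± 0.46 and 3.20 ± 0.48, and PANX2, a channel protein, by 5.13 ± 0.70. ANKRD1 fell by 5.32 ± 0.84 (44.5 ± 6.56 against 1752 ± 218 TPM), and EDN1, the vasoconstrictor endothelin, fell by 3.31 ± 0.58 (102 ± 24.0 against 992 ± 133 TPM). TK1, a thymidine kinase of dividing cells, fell by 3.34 ± 0.45, and PALMD and TXNRD2, a thioredoxin reductase, fell by 3.66 ± 0.34 and 3.46 ± 0.52. Of the 30 measured cell cycle genes all 30 fell, as did all 30 when adjusted over the list alone, among them BIRC5 (−2.85 ± 0.43) and AURKB (−2.69 ± 0.48). Its camera call (adjusted p = 1.6e-42) had adjusted p = 0.065 with an estimated correlation. Of 22 cholesterol synthesis genes 14 fell and 8 did not pass (17 adjusted over the list alone), with ACAT2 at −2.32 ± 0.29. This call was kept (camera adjusted p = 1.8e-22, and adjusted p = 0.034 with an estimated correlation). Of 13 YAP targets 5 fell, of which CTGF (−3.21 ± 0.63) lost its call without PEG gel replicate 2, and 1 rose and 7 fell adjusted over the list alone (adjusted p = 0.19 with an estimated correlation). Of 18 matrix remodelling genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with the collagenase MMP1 at 2.18 ± 0.39, ADAMTS1 at 2.05 and PLAU at 1.64 (adjusted p = 0.10 with an estimated correlation). In the hypoxia list 4 of 28 rose, among them ADM (1.36), and LDHA fell (−0.77), with 5 and 1 adjusted over the list alone and adjusted p = 0.10 with an estimated correlation. CDKN1A, a brake on the cell cycle, rose by 1.49 ± 0.23 as 1 of 3 among 13 p53 targets, and 3 of 12 heat shock genes rose (5 and 6 adjusted over the lists alone, adjusted p = 0.19 with an estimated correlation for each). The heat shock median, in log2(TPM + 1), was 9.27 and 10.4 in PEG gel replicates 1 and 2 and 8.06 and 8.34 on plastic, so PEG gel replicate 2 stood apart. None of 21 endothelial identity genes rose and 4 fell, a list that was not called. The blood list was called higher than on plastic in PEG gel, in Matrigel gel and on PEG gel (2, 1 and 2 of 14 genes, and 6, 5 and 4 adjusted over the list alone), with adjusted p = 0.35, 0.20 and 0.45 with an estimated correlation. Its median log2(TPM + 1) was 3.56 and 3.80 in the duplicates on plastic, 4.42 and 5.08 in PEG gel, 4.97 and 5.45 in Matrigel gel and 4.16 and 5.78 on PEG gel. In all 760 of 14232 genes changed by edgeR, 326 higher and 434 lower. The count was 404 and 278 without PEG gel replicates 1 and 2, and 506 and 368 without plastic replicates 1 and 2, and LDHA lost its call in 3 fits without 1 library.

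Against Matrigel gel, H1-EC2 in PEG gel had more HMOX1 and SRXN1 and less GJA5 and PRND (n = 2 per group). HMOX1 rose by 2.63 ± 0.39 (444 ± 95.5 against 74.7 ± 21.5 TPM), and SRXN1, a sulfiredoxin, by 2.59 ± 0.32 (129 ± 27.9 against 22.4 ± 7.77 TPM). NRIP3, the carbonyl reductase CBR3 and MAP1A rose by 3.22 ± 0.46, 2.83 ± 0.48 and 2.53 ± 0.35. GJA5, a gap junction protein of arteries, fell by 2.89 ± 0.34 (72.7 ± 5.41 against 558 ± 66.2 TPM), and PRND fell by 3.55 ± 0.43 (13.5 ± 0.997 against 164 ± 16.5 TPM). THSD7A fell by 3.59 ± 0.32 and APLNR, the apelin receptor, by 3.42 ± 0.60 (12.2 ± 0.926 against 136 ± 0.792 TPM). Of 14 arterial genes 4 fell (5 adjusted over the list alone), with GJA4 at −1.50 ± 0.22 and BMX at −2.06, and the call was kept (adjusted p = 0.0497 with an estimated correlation). Of 16 interferon response genes 4 fell (11 adjusted over the list alone), with OAS2 at −2.86 ± 0.46 and OAS3 at −1.85 ± 0.25, against adjusted p = 0.056 with an estimated correlation. In the cell cycle list 2 of 30 fell (29 adjusted over the list alone), with BIRC5 at −1.83 and adjusted p = 0.11 with an estimated correlation. SLC7A11, a cystine transporter, rose by 1.78 ± 0.25 as 1 of 2 among 17 unfolded protein and amino acid stress genes (2 adjusted over the list alone, adjusted p = 0.077 with an estimated correlation). The hypoxia list was called higher (median 0.20, adjusted p = 0.0497 with an estimated correlation) although none of its 28 genes passed. Of 12 heat shock genes 3 rose (6 adjusted over the list alone, adjusted p = 0.073 with an estimated correlation). By edgeR 220 genes changed, 94 higher and 126 lower. The count was 134 and 45 without PEG gel replicates 1 and 2, 67 without Matrigel gel replicate 2 and 340 without replicate 1 on PEG gel, and the calls on APLNR, BMX and BIRC5 were lost in at least 1 such fit.

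H1-EC2 in Matrigel gel, against coated plastic, rose in interferon genes and fell in YAP target and cholesterol synthesis genes (n = 2 per group). OAS2, an antiviral synthetase, rose by 3.79 ± 0.49 (12.5 ± 3.24 against 0.89 ± 0.651 TPM) and STC1 by 2.99 ± 0.37 (148 ± 31.6 against 17.5 ± 7.36 TPM). CTGF, a matrix-associated growth factor, fell by 5.02 ± 0.69 (49.6 ± 13.0 against 1515 ± 355 TPM), ANKRD1 by 5.29 ± 0.84 and EDN1 by 4.99 ± 0.63 (33.1 ± 4.07 against 992 ± 133 TPM). TXNRD2 fell by 5.76 ± 0.66. Of 22 cholesterol synthesis genes 13 fell (20 adjusted over the list alone), a call kept with adjusted p = 0.0076 with an estimated correlation. Of 16 interferon response genes 5 rose (12 adjusted over the list alone), among them MX1 (2.60) and ISG15 (1.70), with adjusted p = 0.032 with an estimated correlation. Of 13 YAP targets 4 fell (6 adjusted over the list alone), with CYR61 at −3.19 and adjusted p = 0.033 with an estimated correlation. In the contractile list only TAGLN fell (−1.48) of 15 (3 adjusted over the list alone), and the call was kept (adjusted p = 0.038 with an estimated correlation). None of the 30 cell cycle genes passed (2 adjusted over the list alone), while the list was called lower with adjusted p = 0.21 with an estimated correlation. Of 9 epithelial genes none passed (2 higher adjusted over the list alone), while the list was called higher with adjusted p = 0.20 with an estimated correlation, its median log2(TPM + 1) being 6.17 and 5.92 in the duplicates in Matrigel gel and 4.94 and 5.17 on plastic. By edgeR 167 genes changed, 81 higher and 86 lower, against 384 by DESeq2. The count was 104 and 66 without Matrigel gel replicates 1 and 2, 66 and 94 without plastic replicates 1 and 2, and 278 without replicate 1 on PEG gel, and MX1, ISG15 and TAGLN lost their calls in at least 1 such fit.

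On top of PEG gel, H1-EC2 rose in CYP1A1, CYP1B1 and interferon genes against coated plastic (n = 2 per group). CYP1A1 rose by 6.23 ± 0.47 (118 ± 0.481 against 1.47 ± 1.22 TPM, q = 2.1e-07), CYP1B1 by 5.31 ± 0.52 and STC1 by 4.72 ± 0.39 (504 ± 41.2 against 17.5 ± 7.36 TPM). IL15RA, a chain of the interleukin 15 receptor, rose by 4.23 ± 0.70. EDN1 fell by 6.63 ± 0.69 (10.9 ± 7.20 against 992 ± 133 TPM), ANKRD1 by 5.37 ± 0.84 and FAM111B by 5.24 ± 0.88. Of 16 interferon response genes 11 rose (15 adjusted over the list alone), with OAS2 at 3.94, MX1 at 3.42 ± 0.49, OAS1 at 3.20 and IFI44 at 3.08, a call kept with adjusted p = 0.022 with an estimated correlation. Of 22 cholesterol synthesis genes 17 fell (19 adjusted over the list alone), with MVD at −2.21 and ACAT2 at −2.18, and adjusted p = 0.0062 with an estimated correlation. Of 15 contractile genes 4 fell, among them TAGLN (−2.20) and TPM1 (−1.57), with 1 higher and 9 lower adjusted over the list alone and adjusted p = 0.022 with an estimated correlation. Of 13 YAP targets 7 fell (9 adjusted over the list alone, adjusted p = 0.061 with an estimated correlation), and 6 of 30 cell cycle genes fell (14 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation). MKI67 stood at 5.95 and 31.1 TPM in the duplicates on PEG gel. Of 9 epithelial genes KRT8 (−1.97) and KRT18 (−1.26) fell (2 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation). The pericyte and mesenchymal list was not called (2 of 16 higher and 2 lower, and 3 and 2 adjusted over the list alone), with PDGFRB at 13.4 ± 0.17 against 5.89 ± 0.403 TPM (1.05 ± 0.48, q = 0.25) and a median log2(TPM + 1) of 4.28 and 5.15 on PEG gel and 3.39 and 3.56 on plastic. By edgeR 717 genes changed, 340 higher and 377 lower, and 418 without either plastic replicate.

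Inside against on top of PEG gel, H1-EC2 had less of the interferon genes (n = 2 per group). CBR3 rose by 4.49 ± 0.55 (13.4 ± 1.66 against 0.605 ± 0.304 TPM) and EDN1 by 3.31 ± 0.61 (102 ± 24.0 against 10.9 ± 7.20 TPM). TGFBR3, a TGF-beta co-receptor, fell by 3.14 ± 0.38 (10.4 ± 6.64 against 99.8 ± 18.4 TPM). Of 16 interferon response genes 10 fell (12 adjusted over the list alone), with OAS1 at −3.40 and OAS2 at −3.01, and the call was kept (adjusted p = 0.023 with an estimated correlation). Of 14 arterial genes GJA5 (−2.49) and GJA4 (−1.64) fell (3 adjusted over the list alone, adjusted p = 0.089 with an estimated correlation). Of 14 tip cell genes 3 rose (5 adjusted over the list alone), with ESM1 at 2.63, PDGFB at 1.76 and ANGPT2 at 1.27, and adjusted p = 0.23 with an estimated correlation. Of 9 epithelial genes 2 rose (3 adjusted over the list alone, adjusted p = 0.089 with an estimated correlation). By edgeR 168 genes changed, 74 higher and 94 lower. The count was 275 without replicate 1 on PEG gel and 98 and 36 without replicates 1 and 2 in PEG gel, and EDN1, OAS1, PDGFB and ANGPT2 lost their calls in at least 1 such fit. With only these 2 groups fitted 22 genes were called, without CBR3, EDN1, ESM1, OAS1 or OAS2.

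HUVEC2 in PEG gel, against coated plastic, fell in cell cycle genes and rose in SMAD6 and APLNR (n = 2 per group). SMAD6, an inhibitor within the BMP pathway, rose by 3.91 ± 0.37 (40.4 ± 3.34 against 3.25 ± 1.82 TPM, q = 1.2e-06). APLNR rose by 4.37 ± 0.73 (12.7 ± 5.98 against 0.555 ± 0.53 TPM), MYCN, a growth-promoting transcription factor, by 5.07 ± 0.81 and ACP5, an acid phosphatase, by 3.61 ± 0.40 (49.2 ± 15.5 against 3.86 ± 1.05 TPM). ITGB4, an integrin chain that binds laminin, rose by 4.54 ± 0.61 but only to 4.84 ± 2.64 TPM. NUF2, a kinetochore protein, fell by 6.31 ± 0.69 (1.50 ± 1.89 against 98.9 ± 12.9 TPM), PTX3, a secreted pentraxin, by 5.18 ± 0.68 (15.8 ± 3.87 against 556 ± 134 TPM), and DKK1, a Wnt inhibitor, by 4.66 ± 0.72. APLN, the ligand of APLNR, fell by 4.89 ± 1.09 (10.8 ± 2.92 against 308 ± 29.4 TPM). Of 30 cell cycle genes 29 fell (30 adjusted over the list alone), with CDC20 at −4.15 ± 0.32, CCNB2 at −4.14 and BUB1 at −4.09, and the call was kept (adjusted p = 0.044 with an estimated correlation). Of 13 p53 targets 8 rose (9 adjusted over the list alone), with TP53INP1 at 1.54 and CDKN1A at 1.37, and adjusted p = 0.25 with an estimated correlation. Of 14 TGF-beta and BMP targets 6 rose and 1 fell (8 and 1 adjusted over the list alone), with SMAD7 at 2.63 and ID2 at 3.16 (adjusted p = 0.25 with an estimated correlation). Of 21 endothelial identity genes 5 rose, with PLVAP at 1.98 ± 0.20 and TIE1 at 1.36 ± 0.16, while 8 rose and 3 fell adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Of 9 venous and lymphatic genes 4 rose (4 adjusted over the list alone), with LYVE1 at 2.68 and NRP2 at 0.96 (adjusted p = 0.25 with an estimated correlation), and of 14 arterial genes 4 rose, with UNC5B at 2.09 and SOX17 at 1.76, and BMX fell (−1.63). The arterial list had 9 higher and 2 lower adjusted over the list alone and adjusted p = 0.38 with an estimated correlation. Of 22 cholesterol synthesis genes 6 fell, ACAT2 (−1.85) among them, and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). Of 13 YAP targets 7 fell and F3, the clotting initiator, rose by 3.19 (8 lower and 3 higher adjusted over the list alone, adjusted p = 0.51 with an estimated correlation). By edgeR 1876 genes changed, 914 higher and 962 lower. The count was 1176 and 1006 without PEG gel replicates 1 and 2 and 1056 without plastic replicate 2, and APLN and ID2 lost their calls in 1 such fit.

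**Figure D2:**
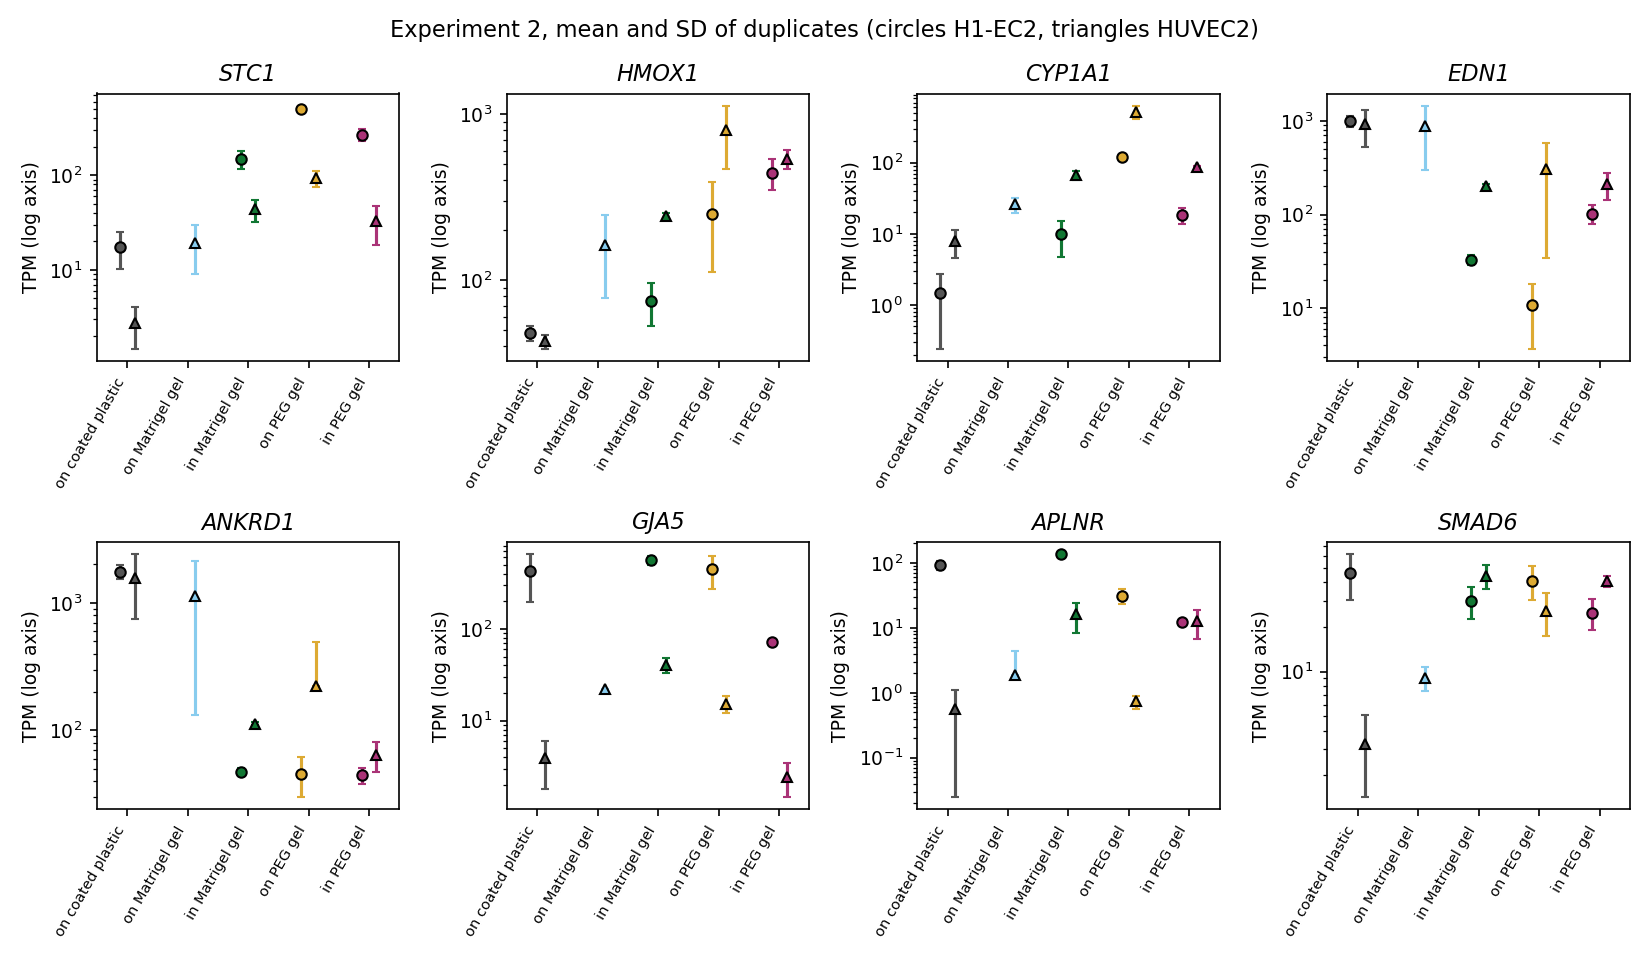
Levels (TPM, log axis) of 8 genes by substrate in experiment 2, each point the mean of duplicates with its SD (no lower bar where the SD exceeds the mean), circles for H1-EC2 and triangles for HUVEC2. SMAD6 in HUVEC2 stood at 40.4 ± 3.34 TPM in PEG gel and 3.25 ± 1.82 TPM on coated plastic, and EDN1 in H1-EC2 at 102 ± 24.0 and 992 ± 133 TPM.

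GJA4, GJA5 and IL33 were lower in HUVEC2 in PEG gel than in Matrigel gel (n = 2 per group). GJA4 fell by 3.44 ± 0.25 (9.47 ± 2.41 against 102 ± 7.31 TPM, q = 3.4e-07) and GJA5 by 4.00 ± 0.40 (2.46 ± 0.997 against 40.4 ± 7.30 TPM), both gap junction proteins of arteries. IL33, a cytokine held in the nucleus, fell by 3.76 ± 0.35 (5.21 ± 2.51 against 66.6 ± 6.86 TPM), TMTC1 by 3.77 ± 0.47 and BMPER, a BMP-binding protein, by 3.84 ± 0.55. MYLK, the myosin light chain kinase, rose by 1.47 ± 0.20 (33.7 ± 1.56 against 12.0 ± 2.91 TPM). CCND1, cyclin D1, rose by 1.60 ± 0.29 (515 ± 16.8 against 170 ± 4.45 TPM) and ANGPT2, a ligand of the TIE2 receptor, by 1.36 ± 0.30. Of 14 arterial genes 3 fell, HEY1 (−1.40) among them, while 2 rose and 5 fell adjusted over the list alone, and adjusted p = 0.075 with an estimated correlation. Of 20 fibrillar matrix genes 3 fell, POSTN (−3.23), COL3A1 (−1.89) and COL6A1 (−1.32), with 3 higher and 6 lower adjusted over the list alone and adjusted p = 0.37 with an estimated correlation. TFPI, a clotting inhibitor, fell by 0.89 as the only 1 of 8 flow-responsive genes (2 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). By edgeR 90 genes changed, 26 higher and 64 lower, against 281 by DESeq2. The count was 29 without Matrigel gel replicate 1 and 10 without PEG gel replicate 2, and of the genes named here only GJA4, GJA5, IL33, TMTC1 and MYLK kept their calls in every fit without 1 library.

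HUVEC2 in Matrigel gel rose in arterial genes and fell in cell cycle genes against coated plastic (n = 2 per group). ITGB4 rose by 7.77 ± 0.63 (44.6 ± 16.8 against 0.185 ± 0.134 TPM), ACP5 by 5.45 ± 0.42 (173 ± 79.3 against 3.86 ± 1.05 TPM) and BMPER by 5.70 ± 0.64. CDC20, an activator of the anaphase complex, fell by 4.99 ± 0.34 (5.67 ± 0.247 against 175 ± 38.8 TPM), APLN by 6.22 ± 1.17 (4.25 ± 1.03 against 308 ± 29.4 TPM) and NCAPH, a condensin subunit, by 5.33 ± 0.47. Of 14 arterial genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with GJA5 at 3.31 ± 0.38, GJA4 at 2.68 ± 0.24 and HEY1 at 2.13. Of 30 cell cycle genes 29 fell (30 adjusted over the list alone), and both calls were kept (adjusted p = 0.023 with an estimated correlation for each). Of 8 flow-responsive genes 3 rose (5 adjusted over the list alone), the transcription factors KLF4 (3.57) and KLF2 (2.15) and the nitric oxide synthase NOS3 (1.43), with adjusted p = 0.062 with an estimated correlation. Of 21 inflammatory genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), with the adhesion molecules SELE at 3.77 and ICAM1 at 2.60 and adjusted p = 0.28 with an estimated correlation. Of 22 cholesterol synthesis genes 11 fell (16 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation). By edgeR 1750 genes changed, 829 higher and 921 lower. The count was 739 without Matrigel gel replicate 1 and 1027 and 971 without plastic replicates 1 and 2, and KLF2 and KLF4 lost their calls in 1 such fit.

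On top of PEG gel, HUVEC2 rose in ITGB4 and ACP5 and fell in cell cycle genes against coated plastic (n = 2 per group). ITGB4 rose by 8.23 ± 0.64 (60.7 ± 16.8 against 0.185 ± 0.134 TPM), ACP5 by 6.93 ± 0.44 (467 ± 36 against 3.86 ± 1.05 TPM, q = 3.0e-08) and CYP1A1 by 6.00 ± 0.43 (520 ± 113 against 7.92 ± 3.38 TPM). MKI67, a proliferation marker, fell by 4.85 ± 0.55 (2.06 ± 1.41 against 60.9 ± 20.5 TPM), and KIF20A and DEPDC1, mitotic genes, fell by 5.42 ± 0.62 and 4.88 ± 0.55. All 30 of 30 cell cycle genes fell (30 adjusted over the list alone), and 5 of 8 flow-responsive genes rose, with KLF4 at 3.85, KLF2 at 2.13, NOS3 at 1.71 and THBD at 1.71 (6 higher and 1 lower adjusted over the list alone). Both calls were kept (adjusted p = 0.038 with an estimated correlation for each). Of 14 immediate early genes 7 rose and 1 fell (10 and 1 adjusted over the list alone), with NR4A1 at 4.88 and FOS at 3.82, and of 9 venous and lymphatic genes 5 rose, LYVE1 (3.85) among them (6 adjusted over the list alone). Both of these calls were lost (adjusted p = 0.0501 with an estimated correlation for each). Of 22 cholesterol synthesis genes 15 fell (16 adjusted over the list alone, adjusted p = 0.073 with an estimated correlation), and of 14 arterial genes 8 rose and CXCR4 fell by 1.89 (8 and 1 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). By edgeR 2456 genes changed, 1174 higher and 1282 lower, with 1566 and 1456 without plastic replicates 1 and 2 and 1233 without replicate 2 on PEG gel, and CXCR4 lost its call in 2 fits without 1 library.

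Inside against on top of PEG gel, HUVEC2 had more MYCN and APLNR and less IL33 and FOS (n = 2 per group). MYCN rose by 7.41 ± 1.01 (12.6 ± 4.98 against 0.07 ± 0.099 TPM) and APLNR by 4.07 ± 0.72. IL33 fell by 4.79 ± 0.37 (5.21 ± 2.51 against 135 ± 47.9 TPM) and FOS, an immediate early transcription factor, by 4.56 ± 0.56 (14.3 ± 3.63 against 332 ± 115 TPM). Of 14 tip cell genes 6 rose (6 adjusted over the list alone), with CXCR4 at 3.03 and NID2 at 1.86, and adjusted p = 0.11 with an estimated correlation. The flow-responsive list was lower with TFPI (−1.27) the only 1 of 8 to pass (3 adjusted over the list alone), a call kept with adjusted p = 0.044 with an estimated correlation. Of 14 immediate early genes 3 fell (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). By edgeR 331 genes changed, 153 higher and 178 lower, with 200 and 141 without replicates 1 and 2 in PEG gel and 162 without replicate 2 on PEG gel.

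On Matrigel gel against coated plastic, HUVEC2 rose in few genes and fell in none by edgeR (n = 2 per group). ITGB4 rose by 4.36 ± 0.61 (4.26 ± 0.12 against 0.185 ± 0.134 TPM), LAMB3, a laminin chain, by 3.50 ± 0.60 (16.1 ± 0.148 against 1.41 ± 1.26 TPM) and ACP5 by 2.91 ± 0.40 (30.4 ± 11.9 against 3.86 ± 1.05 TPM). Of 14 arterial genes GJA5 (2.41) and GJA4 (2.15) rose (6 adjusted over the list alone), a call kept with adjusted p = 0.0095 with an estimated correlation. The immediate early list was also higher, with FOS (2.65) the only 1 of 14 to pass (5 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation). PLVAP, a protein of endothelial vesicles, rose by 1.75. By edgeR 32 genes rose and 0 fell, with 1038 genes at unadjusted p below 0.05, and DESeq2 called 126 (116 higher, 10 lower). The count was 20 and 55 without Matrigel gel replicates 1 and 2 and 17 without plastic replicate 2, and LAMB3, GJA5 and FOS lost their calls in at least 1 fit without 1 library.

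**Figure D3:**
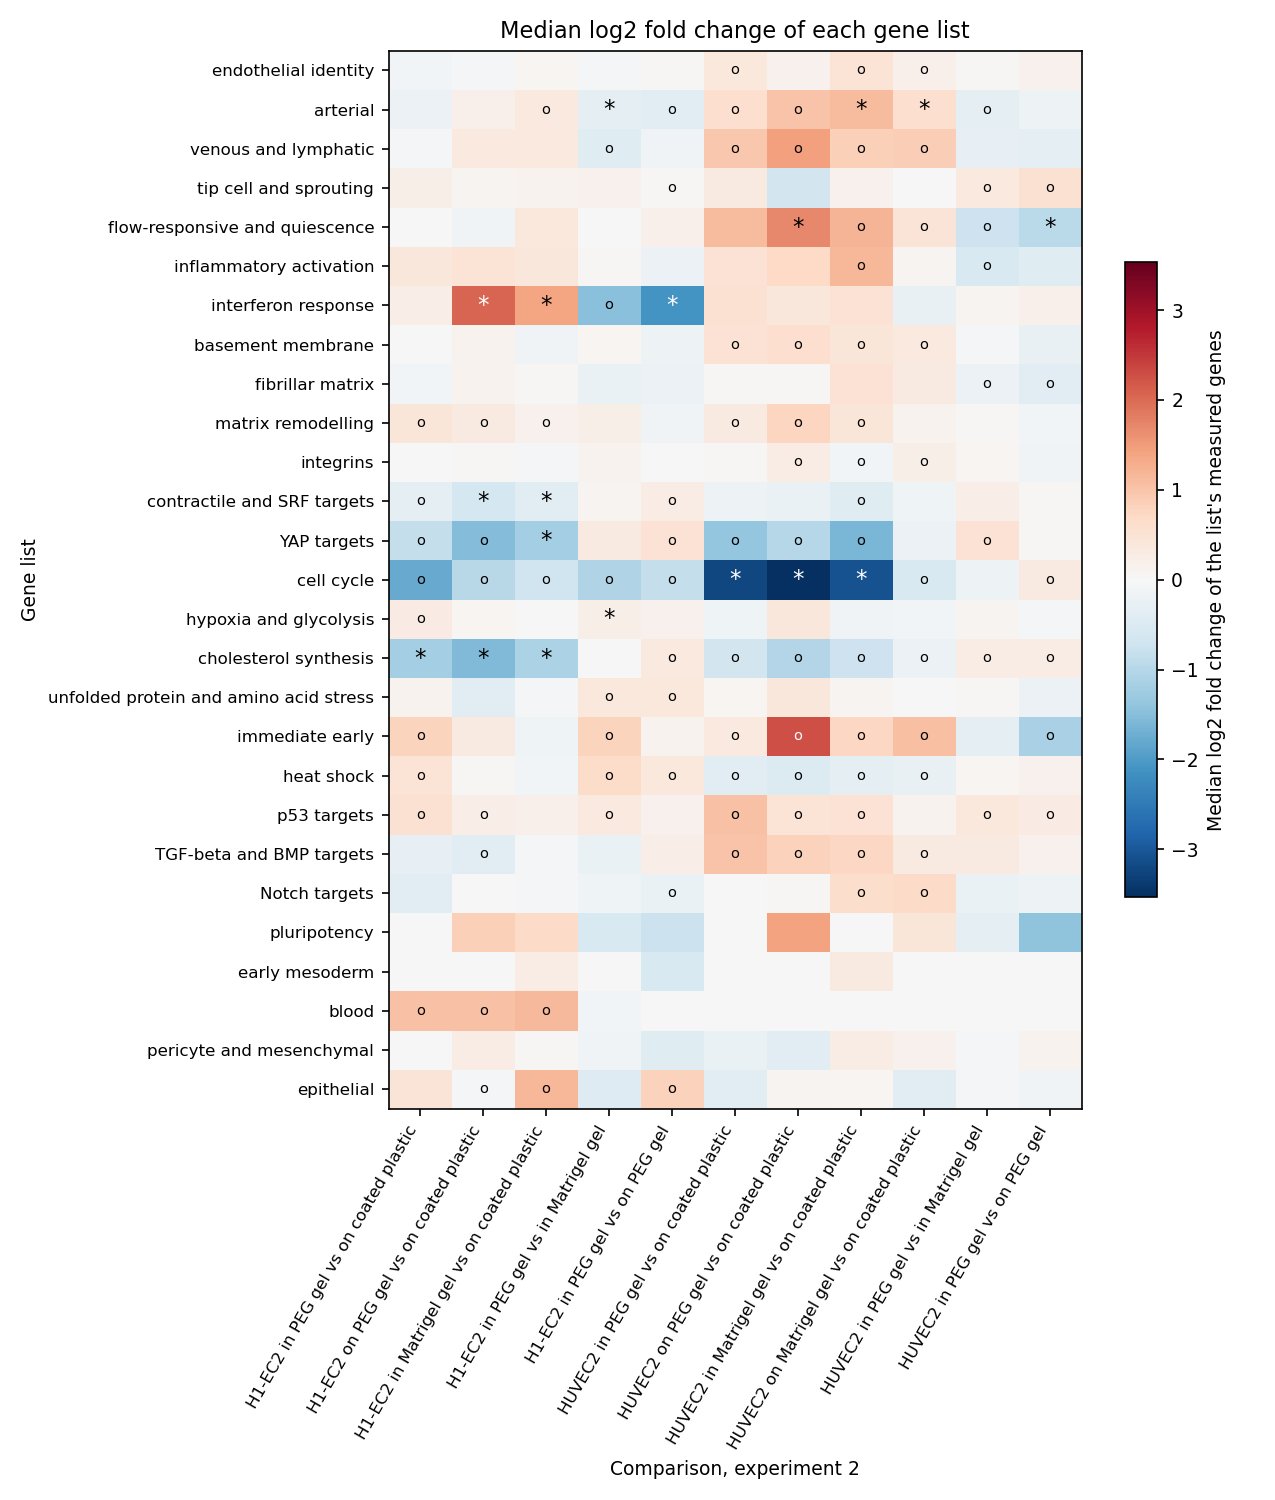
Median log2 fold change (colour) of each gene list (vertical axis) in the comparisons within each cell type of experiment 2 (horizontal axis), with * for calls kept with an estimated correlation and o for calls with the preset correlation only. The cell cycle list was lower in HUVEC2 in PEG gel than on coated plastic (adjusted p = 0.044 with an estimated correlation).

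H1-EC2 had more of the epithelial and cholesterol synthesis genes and less MGP and HOXA9 than HUVEC2 over the mean of 4 shared substrates (n = 8 libraries per cell type, 2 on each substrate). The SD of levels here thus holds differences between substrates as well as between duplicates. RHAG, a red cell membrane protein, was higher by 9.15 ± 0.46 (28.2 ± 15.3 against 0.074 ± 0.097 TPM), and MYB and IKZF1, transcription factors of blood cells, by 8.67 ± 0.42 and 9.02 ± 0.46. DLK1, a Notch ligand homologue, was higher by 8.92 ± 0.42 (51.0 ± 34.3 against 0.075 ± 0.076 TPM), and DSC2, a desmosomal cadherin, by 8.73 ± 0.21 (54.0 ± 9.65 against 0.146 ± 0.119 TPM). MGP, a matrix protein that limits calcification, was lower (−7.93 ± 0.15, 1.88 ± 0.584 against 404 ± 155 TPM), and HOXA9, a positional transcription factor, stood at 0.299 ± 0.154 against 63.2 ± 9.91 TPM (−7.95 ± 0.20). HOXA5 and HOXA7 were lower too (−8.36 ± 0.40 and −7.64 ± 0.29), as was CFI, a complement regulator (−7.51 ± 0.17). All 9 epithelial genes were higher (9 adjusted over the list alone), with DSP at 7.83 ± 0.17 and EPCAM at 6.92, as were all 22 cholesterol synthesis genes (22 adjusted over the list alone), HMGCS1 at 2.74. Of 16 pericyte and mesenchymal genes 9 were higher and 5 lower (9 and 5 adjusted over the list alone), with CSPG4 at 7.44 and THY1 at 7.18. Of 13 pluripotency genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone), the higher ones holding the RNA-binding LIN28B (7.68) and LIN28A (5.14) and DPPA4 (6.02). These 4 calls were kept (adjusted p = 0.0026, 0.026, 0.026 and 0.049 with an estimated correlation). All 14 blood genes were higher (14 adjusted over the list alone), with adjusted p = 0.075 with an estimated correlation. Of 14 arterial genes 12 were higher (12 adjusted over the list alone), with GJA5 at 4.82 ± 0.19, and BMX, a kinase gene, was lower (−7.01), at adjusted p = 0.052 with an estimated correlation. Of 16 interferon response genes 8 were lower, with IFI27 at −6.68, and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation). By edgeR 7328 genes differed, 4221 higher and 3107 lower, with a median of 0.11 over all genes. Medium and oxygen are not stated for experiment 2, so they may differ with the cell type as well as with the substrate.

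Genes whose change from coated plastic to PEG gel differed between the cell types included APLNR, SMAD6 and DYNC1I1 (n = 2 in each of 4 groups). APLNR had an interaction of −7.33 ± 0.94 (q = 0.00026), with 12.2 ± 0.926 against 92.6 ± 13.5 TPM in H1-EC2 and 12.7 ± 5.98 against 0.555 ± 0.53 TPM in HUVEC2. SMAD6 had −4.83 ± 0.48 (q = 2.1e-05), with 24.9 ± 5.93 against 45.9 ± 15.7 TPM in H1-EC2 and 40.4 ± 3.34 against 3.25 ± 1.82 TPM in HUVEC2. DYNC1I1, a dynein chain, had 6.55 ± 1.1 (34.9 ± 16.0 against 7.89 ± 0.516 TPM in H1-EC2), and CD200, a membrane glycoprotein, had −4.84 ± 0.96. Of 14 TGF-beta and BMP targets 4 passed below 0 (1 above and 7 below adjusted over the list alone), with SMAD7 at −3.06 and ID1 at −2.48, and adjusted p = 0.092 with an estimated correlation. Of 12 heat shock genes 4 passed above 0 (11 adjusted over the list alone), with HSP90AA1 at 1.45, and adjusted p = 0.095 with an estimated correlation. Of 30 cell cycle genes 6 passed above 0 (18 adjusted over the list alone), with CDC20 at 2.36 and BUB1 at 2.91, both having fallen less far in H1-EC2, and adjusted p = 0.25 with an estimated correlation. Of 21 endothelial identity genes 4 passed below 0 and 1 above (9 and 1 adjusted over the list alone), with PLVAP at −1.71 and ENG at −1.47, and adjusted p = 0.092 with an estimated correlation. In all 350 genes passed (131 above and 219 below 0), of which 243 had opposite signs in the 2 cell types, 84 the same sign and a larger change in HUVEC2 and 23 the same sign and a larger change in H1-EC2. These signs were read from the estimated changes, whether or not either change was called. Across genes the 2 changes correlated at 0.152 (Pearson) and 0.253 (Spearman), and genes are not independent replicates. Called higher in both were 125 genes, against 20.9 if the calls were unrelated, and lower in both 249 against 29.3. Another 25 were called in opposite directions. The count was 197 without H1-EC2 on plastic replicate 1, 158 without H1-EC2 in PEG gel replicate 2, 231 and 203 without HUVEC2 in PEG gel replicates 1 and 2 and 214 without HUVEC2 on plastic replicate 2, and SMAD7 and HSP90AA1 lost their calls in at least 1 such fit.

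In experiment 1, H1-EC1 on plastic differed from H1 stem cells in endothelial and pluripotency genes (1 library each, no replicate check and no test). PLVAP stood at 1104 against 0.18 TPM (log2 ratio 9.87), CDH5 and PECAM1 at ratios of 9.29 and 8.73, VWF at 6.41 and KDR at 4.11. POU5F1 stood at 2.62 against 3781 TPM (−10.03), with TDGF1, a co-receptor of early embryos, at −8.64 and NANOG at −6.89. MMP1 was at 1979 TPM in H1-EC1 and 0 in stem cells, and L1TD1 at 0 and 454 TPM. Of 21 endothelial identity genes 20 were over 2-fold higher (median 6.41, above all of 10000 random lists, percentile 100), and of 15 pluripotency genes 15 were lower (median −5.93, percentile 0). Of 9 epithelial genes 6 were lower (median −4.27) and of 21 cholesterol synthesis genes 14 higher (median 1.30). In all 4649 of 11188 genes differed over 2-fold, 2642 higher and 2007 lower. The stem cell column did not match the other columns on 561 gene entries, which were left out.

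H1-EC1 in PEG gel had more HPGD and less MGP than HUVEC1 in PEG gel, with days 1, 2 and 3 as blocks (n = 3 per cell type). HPGD, which breaks down prostaglandins, was higher by 11.35 ± 0.24 (131 ± 30.5 against 0.04 ± 0.069 TPM), and CBLN1, a secreted protein, stood at 112 ± 39 TPM against 0. MGP was lower (−12.68 ± 0.30, 0.083 ± 0.144 against 560 ± 405 TPM), as was PMCH, a hormone precursor (−12.81 ± 0.29), and HOXA10 stood at 0 against 22.8 ± 2.19 TPM. Arterial genes were mostly higher, 11 of 14 with 1 lower (11 and 1 adjusted over the list alone), with GJA4 at 6.82 ± 0.28, GJA5 at 5.96 and BMX at −6.00. Of 21 cholesterol synthesis genes 18 were higher and 1 lower (18 and 1 adjusted over the list alone). Of 13 YAP targets 11 were lower and 2 higher (11 and 2 adjusted over the list alone), with CTGF at −3.21, of 14 integrins 8 lower and 3 higher (9 and 3 adjusted over the list alone), with ITGB4 at −5.96, and of 13 interferon response genes 8 lower and 1 higher (8 and 1 adjusted over the list alone), with IFI44 at −6.39. Each of these 5 camera calls had adjusted p = 0.63 with an estimated correlation, a test that could hardly pass at 2 residual degrees of freedom. By edgeR 5828 of 12569 genes differed, 2893 higher and 2935 lower, and 3813 without day 2. Across 12403 genes this difference and that between H1-EC2 and HUVEC2 correlated at 0.744 (genes are not independent replicates), with 1783 higher in both, 1779 lower in both and 396 opposite.

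The co-culture of H1-EC1 with pericytes in PEG gel held inflammatory genes far above a mixture of its 2 monocultures (n = 3 days, limma-trend). PTGS2, the inducible cyclooxygenase, was higher by 7.90 ± 0.10 (571 ± 82.4 TPM against 1.57 ± 0.405 in H1-EC1 and 2.55 ± 1.42 in pericytes, q = 1.4e-07). The chemokine IL8 was higher by 6.65 ± 0.17 (967 ± 241 TPM against 8.23 and 8.75), the cytokine IL11 by 6.17 ± 0.11 and CSF3, a granulocyte growth factor, by 5.88 ± 0.09. PTGDS, a prostaglandin synthase of pericytes, was lower (−3.07 ± 0.33, 39.6 against 795 TPM in pericytes), as were SLC14A1, a urea transporter (−3.20 ± 0.18), and EMCN, an endothelial sialomucin (−1.03). Of 20 inflammatory genes 18 were higher (20 adjusted over the list alone, median 2.71), among them IL1B (5.72), CXCL1 (5.69) and LIF (4.43). Of 29 hypoxia genes 22 were higher (23 adjusted over the list alone), with VEGFA, the endothelial growth factor, at 1.73, and of 8 Notch targets 4 (5 adjusted over the list alone), with HEYL at 3.72. Of 13 p53 targets 6 were lower (10 adjusted over the list alone) and of 21 endothelial identity genes 2 were lower (2 higher and 3 lower adjusted over the list alone). Gene lists were counted here without a list test. The mixtures were fitted with H1-EC1 shares of the RNA of 60.5%, 47.5% and 50.5% on days 1, 2 and 3. The error of these shares was not measured. In all 1460 of 11488 genes differed, 798 higher and 662 lower (54.7% higher against 35.4% with unscaled libraries, where the median of all genes moved from −0.034 to −0.14). Without day 2 the count was 386, and PTGDS and HEYL lost their calls in at least 1 fit without a day.

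**Figure D4:**
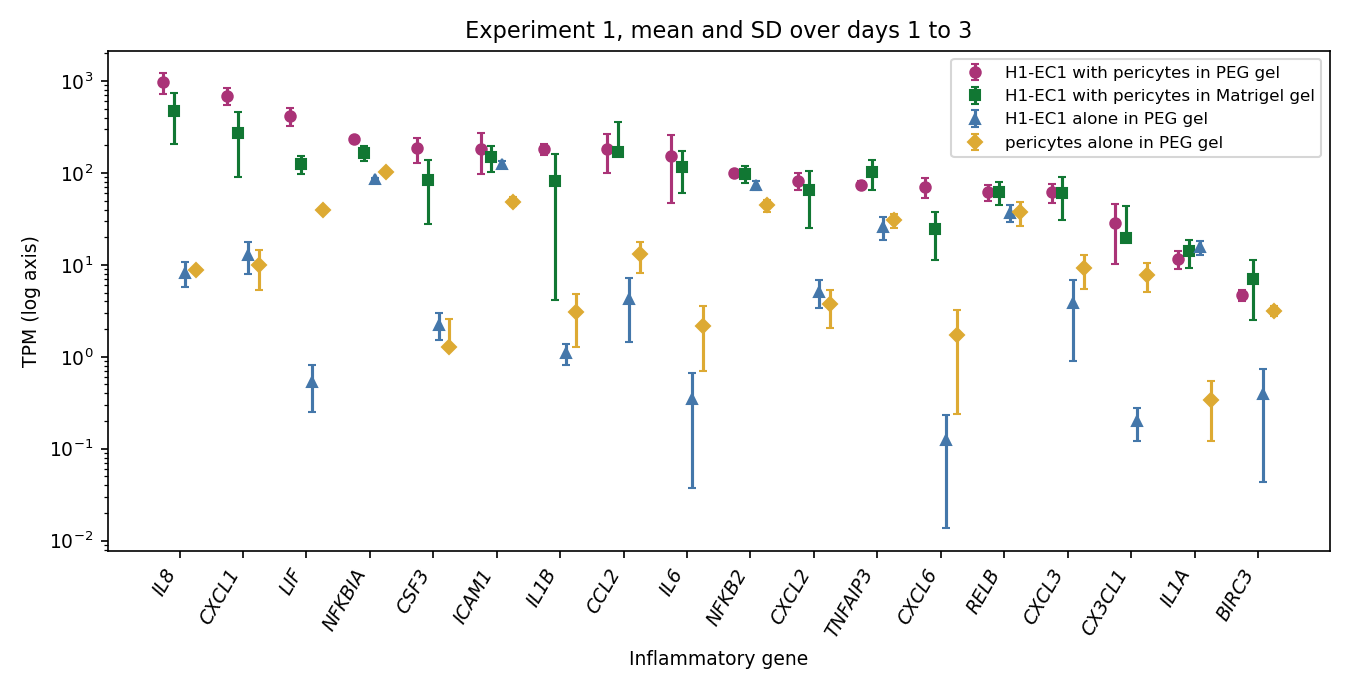
Levels (TPM, log axis) of 18 inflammatory genes (horizontal axis) in experiment 1, each point the mean over days 1 to 3 with its SD (no lower bar where it exceeds the mean) for the co-culture in PEG gel, the co-culture in Matrigel gel, H1-EC1 alone and pericytes alone. IL8 stood at 967 ± 241 TPM in the co-culture in PEG gel and at 474 ± 269 TPM in Matrigel gel.

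In Matrigel gel the co-culture had less PTGS2 and TNFAIP6 than in PEG gel, with days as blocks (n = 3 per gel). PTGS2 fell by 3.87 ± 0.29 (41.7 ± 15.8 against 571 ± 82.4 TPM), TNFAIP6, a hyaluronan-binding protein, by 3.67 ± 0.20 (8.52 ± 1.97 against 106 ± 15.4 TPM) and C2CD4A by 3.69 ± 0.17. MKI67 rose by 2.32 ± 0.22 (14.2 ± 9.73 against 2.50 ± 1.22 TPM), and SLC8A1, a sodium and calcium exchanger, by 1.75 ± 0.20. Of 30 cell cycle genes 6 rose (28 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation). Of 29 hypoxia genes 4 fell (12 adjusted over the list alone), with CA9 at −1.63, VEGFA at −1.46 and adjusted p = 0.44 with an estimated correlation. Of 16 pericyte and mesenchymal genes 4 fell and CSPG4 rose by 0.87 (9 and 3 adjusted over the list alone), with PDGFRA at −2.18 ± 0.13 and FOXC1 at −1.41 (adjusted p = 0.44 with an estimated correlation). LIF was the only 1 of 21 inflammatory genes to fall (−1.76, and 1 adjusted over the list alone) in a list called lower with adjusted p = 0.56 with an estimated correlation. By edgeR 242 of 13217 genes changed, 56 higher and 186 lower, against 466 by DESeq2. The count was 434, 964 and 32 without days 1, 2 and 3, and of the genes named only PTGS2, TNFAIP6, C2CD4A, PDGFRA and FOXC1 kept their calls in each of these fits. Cell density also differed between the gels. At 2 residual degrees of freedom the list tests with an estimated correlation could hardly pass.

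Crosslinking of the PEG gel came with small changes in the co-culture, HEYL and HEY2 among them (11 libraries of 35, 50 and 60% crosslinking, day as a factor). HEYL, a Notch-driven repressor, fell by 0.30 ± 0.06 for each 10 percentage points, HEY2 by 0.22 ± 0.05 and NRARP by 0.13 ± 0.03. AGRN, a basement membrane proteoglycan, fell by 0.18 ± 0.04 and COL6A3, a collagen chain, by 0.20 ± 0.04. Of 8 Notch targets 3 fell (5 adjusted over the list alone, camera adjusted p = 8.9e-07), with adjusted p = 0.16 with an estimated correlation. None of 13 p53 targets passed, 6 rose adjusted over the list alone, and that list too had adjusted p = 0.16 with an estimated correlation. By edgeR 207 of 13568 genes changed, 104 higher and 103 lower, with 0 past a change of 1 on the log2 scale. All the named genes lost their calls in at least 1 fit without a day, the count was 109 and 26 without days 1 and 2, and with all 25 gels fitted together it was 0. In the fit of 11 libraries 1426 genes had an unadjusted p below 0.05, and DESeq2 called 241 there.

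Without CRGDS, the adhesion peptide, the co-culture library differed from the 2 mM library in few genes (1 library each, no replicate check and no test). AKR1C3, an aldo-keto reductase, stood at 56.3 against 25.2 TPM (log2 ratio 1.13) and the chromatin protein BMI1 at a ratio of 1.03. LTB, a lymphotoxin, stood at 15.4 against 37.7 TPM (−1.24) and LBH at 204 against 385 TPM (−0.91). The median of the endothelial identity list was −0.26 and of the Notch targets −0.42, below all of 10000 random lists (percentile 0), and that of the inflammatory list 0.30, above all of them (percentile 100). Libraries with 2 mM CRGDS differed by similar amounts on the same day. The endothelial identity median, in log2(TPM + 1), was 8.37 at 0 mM and 8.62, 8.39 and 8.42 at 2 mM with 50, 35 and 60% crosslinking, the inflammatory median 6.91 against 6.51, 6.90 and 7.04, and the Notch median 6.07 against 6.35, 6.49 and 5.71, so these shifts cannot be ascribed to CRGDS. In all 39 of 10907 genes differed over 2-fold, 25 higher and 14 lower, beside 37 for 50 against 35% and 25 for 50 against 60% crosslinking.

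Across H1-EC1, HUVEC1 and pericytes, PEG gel on day 1 came with more NR4A1 and less MKI67 transcript than coated plastic (n = 3, cell type as a block). NR4A1 and NR4A3, nuclear receptors of the immediate early response, rose by 4.72 ± 0.52 (83.8 ± 57.6 against 2.43 ± 0.727 TPM) and 4.76 ± 0.69. MKI67 fell by 4.82 ± 0.25 (1.89 ± 0.785 against 56.3 ± 40.9 TPM), MYBL2, a cell cycle transcription factor, by 4.50 ± 0.20 and KIF20A by 4.48 ± 0.26. Of 30 cell cycle genes 21 fell (28 adjusted over the list alone, camera adjusted p = 9.4e-71), with adjusted p = 0.54 with an estimated correlation. Of 13 immediate early genes 3 rose, JUNB (1.66) among them (4 higher and 1 lower adjusted over the list alone), and of 13 YAP targets 2 fell, with ANKRD1 at −3.95 (7 adjusted over the list alone), each with adjusted p = 0.54 with an estimated correlation. EMCN rose by 3.29 ± 0.27 as the only 1 of 21 endothelial identity genes (1 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation). With 2 residual degrees of freedom the test with an estimated correlation could hardly pass for any list. By edgeR 396 of 12664 genes changed, 123 higher and 273 lower, or 31.1% higher against 45.5% with DESeq2, which called 1927 and moved the median of all genes from 0.015 to 0.12. The count was 0 without H1-EC1 and 0 without HUVEC1, where every named call was lost in fits of 2 pairs of libraries, and oxygen and in part the medium differed with the substrate.

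With time in PEG gel, H1-EC1 gained NOV and lost APLNR transcript (14 libraries of 4 cultures, slope per day). NOV, a matrix-associated protein, rose by 1.16 ± 0.10 per day (q = 0.00067), while APLNR fell by 1.31 ± 0.22, the secreted SCUBE1 by 1.33 ± 0.27 and MKI67 by 1.04. Of 30 cell cycle genes 13 fell (19 adjusted over the list alone), of 13 YAP targets 5 (6 adjusted over the list alone), AMOTL2 (−0.71) among them, and of 22 cholesterol synthesis genes 9 (12 adjusted over the list alone). Each of these 3 had adjusted p = 0.29 with an estimated correlation. By edgeR 677 of 13856 genes changed, 254 higher and 423 lower, with 161, 409 and 123 without days 1, 2 and 5, and of the named genes only NOV kept its call throughout. Over the mean of the 4 cultures EBF3 and MCF2L rose by 1.01 ± 0.13 and 1.00 ± 0.20 per day, and BNIP3 and LDHA, genes raised by low oxygen, fell by 0.56 and 0.46. Of 29 hypoxia genes 16 fell and EGLN3, an oxygen sensor, rose by 0.60 (19 and 1 adjusted over the list alone), with adjusted p = 0.57 with an estimated correlation. The arterial genes CXCR4 (0.56), UNC5B (0.50) and DLL4 (0.46) rose, as 3 of 5 among 14 with 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). The mean trend held 2044 called genes, 957 higher and 1087 lower, against 56 without day 3 and 1244 without day 5, and UNC5B alone of the genes named kept its call.

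H1-EC1 in PEG gel had more hypoxia and glycolysis transcript than on Matrigel gel on day 1 (1 library each, no replicate check and no test). AK4, a mitochondrial adenylate kinase, stood at 47.4 against 0.33 TPM (log2 ratio 5.18) and PGM1, a sugar phosphate enzyme, at 90.1 against 8.44 TPM (3.27). HMOX1 stood at 154 against 588 TPM (−1.93), NQO1, a quinone reductase, at 320 against 1195 TPM (−1.90) and OSGIN1 at 4.12 against 23.5 TPM (−2.26). Of 27 hypoxia genes 21 were over 2-fold higher (median 1.40, percentile 100 among 10000 random lists), and of 15 inflammatory genes 10 (median 1.13, percentile 99.9). By TPM 2219 of 10376 genes differed over 2-fold, 2089 higher and 130 lower (94.1% higher), and with TMM-scaled counts 1924, 1061 higher and 863 lower (55.1% higher), as the median of all genes moved from 0.29 to −0.12. The gel cultures were kept at 1.5% oxygen and those on Matrigel were normoxic.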

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

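The interaction of cell type with the change from coated plastic to PEG gel was planned, and no test in this part was chosen after its result was seen. For the 350 genes whose substrate effect differed between H1-EC2 and HUVEC2, the effect of the gel is to be read for each cell type. Among the genes that met the naming rule APLNR, the apelin receptor, had the largest difference below 0 (−7.33), falling in H1-EC2 and rising in HUVEC2. SMAD6, an inhibitor within the BMP pathway (−4.83), and CD200, a membrane glycoprotein (−4.84), also fell in H1-EC2 relative to HUVEC2. ELAVL2, an RNA-binding protein (−4.92), lay at 7.65 against 15.0 TPM in H1-EC2 and at 0.685 against 0.035 TPM in HUVEC2. DYNC1I1, a dynein chain, had 6.55, and TNFSF18, a ligand of the tumor necrosis factor family, had 6.18 with 6.16 ± 2.15 against 118 ± 64.4 TPM in HUVEC2 (SD, n = 2). ELAVL2 and TNFSF18 lost their calls in several fits without 1 library, the other 4 in none.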

How the results depend on the processing

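Added after results were seen were the fits without H1-EC2 on PEG gel replicate 1 in comparisons that do not hold this group and the 2 treatments of the out-of-step stem cell entries (4930 genes over 2-fold with all entries as deposited and 4756 in byte order of the symbols, against 4649). These added fits gave the upper end of most of the ranges of experiment 2 below. No other library outside a comparison was left out. The counts of called genes moved with single libraries: without 1 library at a time they ranged, for H1-EC2, over 278 to 936 (in PEG gel against plastic), 45 to 340 (PEG against Matrigel gel), 66 to 278 (in Matrigel gel against plastic), 418 to 791 (on PEG gel against plastic) and 36 to 275 (in against on PEG gel). For HUVEC2 the same 5 ranges were 1006 to 2104, 10 to 130, 739 to 1976, 1233 to 2703 and 141 to 469, with 17 to 55 on Matrigel gel and 158 to 489 for the interaction. In experiment 1, without 1 day or cell type at a time, they were 3813 to 6048 (H1-EC1 against HUVEC1), 32 to 964 (Matrigel against PEG gel), 26 to 217 (crosslinking), 0 to 349 (PEG gel against plastic), 123 to 557 (H1-EC1 trend), 56 to 1814 (mean trend) and 386 to 1618 (mixture). With no filter on low counts the H1-EC2 counts in the same order were 1248, 673, 552, 1321 and 565, those of HUVEC2 430 (PEG against Matrigel gel), 774 (in against on PEG gel) and 204 (on Matrigel gel), the interaction 831 and Matrigel against PEG gel in experiment 1 406. DESeq2 called 459 (PEG against Matrigel gel), 384 (in Matrigel gel), 1132 (on PEG gel) and 403 (in against on PEG gel) for H1-EC2, 281, 656 and 126 for the 3 HUVEC2 comparisons just named, 675 for the interaction, and 466 (Matrigel against PEG gel) and 1927 (PEG gel against plastic) in experiment 1. With only the groups compared, H1-EC2 gave 440 (PEG against Matrigel gel), 259 (in Matrigel gel), 366 (on PEG gel) and 22 (in against on PEG gel), HUVEC2 273 (PEG against Matrigel gel) and 15 (on Matrigel gel), and the interaction 565. With the replicate number as a block every count of experiment 2 rose, among them to 293 (H1-EC2 in against on PEG gel), 144 (HUVEC2 PEG against Matrigel gel) and 74 (HUVEC2 on Matrigel gel). Residuals of equal replicate numbers correlated at a median of 0.012 over 36 pairs of groups, so over all genes the numbers showed no pairing. This does not exclude a replicate effect in part of the genes. All 25 gels in 1 fit gave 483 (Matrigel against PEG gel), 0 (crosslinking) and 5388 (mean trend), and could not be run for the H1-EC1 trend or PEG gel against plastic. That fit turned the mean trends of DSC2 (1.17 to −0.038), FOS (to −0.17), IFIT1 (to 0.021) and VWF (to −0.25), and DSC2 ran from −0.85 without day 3 to 2.53 without day 1. For 0 against 2 mM CRGDS the 39 genes became 66 and 12 with pseudocounts of 0.1 and 5, and 140 with genes from 1 TPM, and H1-EC1 in PEG gel against on Matrigel gel gave 1245 with a pseudocount of 5. Unscaled counts moved the share of higher genes in the mixture comparison from 54.7 to 35.4%. Of 208 list calls 22 were kept with an estimated correlation and 115 with fry, none with another direction. The 208 include calls from fits of experiment 1 with 2 residual degrees of freedom, where an estimated correlation could hardly keep any. Except for the filters and pseudocounts, which add or remove weakly expressed genes, the cause of these moves was not tested. Splits of the libraries at random asked how often a count as large arises by chance. For H1-EC2 against HUVEC2 (6095 with substrate blocks, highest other 3826) only the real one of 60 splits reached it. These splits treat libraries as exchangeable, which duplicates of unstated origin may not be, so they do not exclude chance. For crosslinking (207) the real one of 60 splits alone reached it too. Another split came near it (189) and the fit of all 25 gels called 0, so chance is not excluded there either. For H1-EC1 against HUVEC1 (5828), Matrigel against PEG gel (242) and PEG gel against plastic (396) the highest other was 0, and 10 splits are too few for a share under 0.05.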

Other observations

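The NRF2 gene list and its tests were added after the oxidative stress genes had been seen, with predictions written before the tests were run except those on HMOX1 alone and on CBR3 and TXNRD1; the co-culture share test and the tests of the stem cell column were written after their results were in view. In the co-culture of H1-EC1 with pericytes, some transcripts of secreted inflammatory proteins reached high levels in both gels. Others stayed lower, such as CXCL6 and CX3CL1 at 24.5 ± 13.3 and 19.8 ± 23.5 TPM in the Matrigel co-culture. CXCL1, a chemokine, stood at 695 TPM in the PEG co-culture (mean over 3 days) against 12.9 in H1-EC1 and 9.99 in pericytes, and CCL2, another chemokine, at 181 ± 81.6 TPM (SD, n = 3 days) against 4.29 and 13.0. IL8 in the Matrigel co-culture stood at 474 ± 269 TPM. IL1A alone of the 18 called genes did not exceed both monocultures in PEG gel (11.6 against 15.5 TPM in H1-EC1).

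The interaction of cell type with the change from coated plastic to PEG gel (H1-EC2 relative to HUVEC2) was read for targets of NRF2. NRF2 is the oxidative stress factor. Of 8 genes seen first 5 had a called interaction above 0, as did 3 of 23 targets not seen before. The list of 23 had camera p = 0.085 with an estimated correlation. The 8 genes were chosen after results holding H1-EC2 in PEG gel had been seen, and this interaction holds that group too. Their count is therefore no independent support. SRXN1 had an interaction of 2.36 ± 0.43 (edgeR adjusted p = 0.0049), TXNRD1, a thioredoxin reductase, of 1.96 ± 0.31 (adjusted p = 0.0017) and SLC7A11 of 2.05 ± 0.34 (adjusted p = 0.0024). HMOX1 and NQO1 did not share this, with −0.43 ± 0.52 (adjusted p = 0.80) and −0.16 ± 0.28 (adjusted p = 0.90) and rises of 3.61 ± 0.40 and 0.97 ± 0.20 in HUVEC2, and OSGIN1 did not pass (adjusted p = 0.13).

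A wrong RNA share of the 2 cell types was tested as a cause of the inflammatory genes, since no share can exceed the higher monoculture. Of the 18 genes 17 lay above both monocultures on all 3 days, so a wrong RNA share is unlikely. A higher total cell density was tested with the Matrigel co-culture, which was seeded at a lower density, and 15 of the 18 lay above both there. As the material differed too, the higher total cell density of the co-culture could still have contributed.

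Light and photoinitiator acting alike on both cell types were tested as a cause of the NRF2 genes with the 23 targets not seen before. They were higher in PEG gel than on plastic in H1-EC2, with 9 of 23 genes called by edgeR, and also in HUVEC2, with 4 of 23 called (camera adjusted p = 0.0077, and p = 0.11 with an estimated correlation). Their interaction lay above 0 at the preset correlation (camera p = 0.0024, median 0.36, 3 called) but did not pass with an estimated correlation (p = 0.085), so light and photoinitiator stay open for these targets. CBR3 and TXNRD1 fell in HUVEC2 (−1.67 ± 0.41 and −0.82 ± 0.22, edgeR adjusted p = 0.010 and 0.015), which an effect alike in both cell types would not give. These 2 of the 8 genes seen first were picked after their values were in view, and HMOX1 and NQO1 rose in both cell types. Light and photoinitiator are therefore not excluded. The rise of CBR3 in H1-EC2 did not pass (1.45 ± 0.43, edgeR adjusted p = 0.057). For CBR3 the difference between the cell types rests on its interaction (3.13 ± 0.60, edgeR adjusted p = 0.0067). Contact with PEG alone was tested by in against on PEG gel, where the 23 targets were higher inside (camera p = 2.0e-08, and p = 0.0057 with an estimated correlation, 1 called). They were also higher on PEG gel than on plastic, in H1-EC2 (camera p = 0.0088, 4 called, and p = 0.13 with an estimated correlation) and in HUVEC2 (camera p = 7.3e-07, 9 called, and p = 0.011 with an estimated correlation). Cells inside touch the gel on all sides, so a rise inside does not exclude contact, which stays open. For HMOX1 alone the rise on PEG gel against plastic (2.28 ± 0.38) was in line with contact with the PEG material, but of the 8 genes seen first only HMOX1 and SLC7A11 were called higher there, 5 did not pass and CBR3 was lower (−3.03 ± 0.57, adjusted p = 0.0027). Whether light reached cells on top of gels is not stated. In experiment 1, H1-EC1 in PEG gel had less HMOX1, NQO1 and OSGIN1 than on Matrigel gel (log2 ratios −1.93, −1.90 and −2.26, 1 library each). These 3 were among its 5 lowest named genes, and oxygen differed there too.

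The stem cell column of experiment 1 was out of step with the other columns on 561 gene entries. As deposited, these entries correlated with the median of the other libraries at 0.392, against 0.866 once put in byte order of the symbols and 0.806 for the remaining genes, which suggests that the column follows another order of genes. In the other 29 libraries the correlation was at least 0.925 as deposited and at most 0.376 in byte order. True differences of stem cells in these genes are unlikely, as the entries were picked by the spelling of their symbols alone.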
